A study of Mus musculus with 6 samples.

How the data were processed

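Total RNA from E14 cells, a mouse embryonic stem cell line, was measured on 6 Illumina mouse BeadChip arrays, 3 from cells given a control shRNA and 3 from cells given shRNAs against Tip5, the protein that the Baz2a gene encodes. Per the labels' protocols, shRNA vectors were electroporated, antibiotic selection started 72 hours later and lasted 6 days, and RNA was taken at passage 3 after each transfection. The cells grew on gelatin in medium with 20% fetal bovine serum and 1000 U/ml LIF. Biotinylated cRNA was hybridised. The labels give 3 transfections per group, and the array number sets the precision.

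Per the file headers, the authors deposited a probe signal and a detection p-value for each array, and GenomeStudio 2011.1 is named in the submitters' processing notes without its role. The deposited signal is a linear intensity with no background subtracted, as the values show, and the detection p-value is taken here as the share of negative control probes at least as bright. A further deposited table holds the authors' processed intensity. Set against the same array's signal, its values above the floor of 1 follow a straight line, a constant subtracted and a factor applied, which gave each array a mean between 538.3 and 538.6. Its column medians were 16.2, 16.4 and 16.6 in control replicates 1, 2 and 3 and 14.6, 15.7 and 19.2 in knockdown replicates 1, 2 and 3. Its scale is linear and its probes are not centred, and it was used only as an alternative. How the authors chose the constants is not given in the sources used here.

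From the probe signals, background was corrected with limma 3.58.1 in R 4.3.3 (normexp, with the background inferred from the detection p-values, offset 16), followed by quantile normalization and log2, which is the neqc procedure. Of 25697 probes, 13064 (50.8%) had a detection p-value under 0.05 on at least 3 of the 6 arrays and were tested. The probe annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719, of which 765 were tested and stand without a name. Symbols were updated through the Entrez identifier with the mouse gene table of assembly GRCm38.p6, which matched 23962 probes and left 16 with their older symbol. The 13064 probes covered 9015 genes. Each gene stands by its tested probe of highest mean level, and other probes of a named gene are stated where their difference lies over 0.1 from it. No coordinates are printed, since no genome build is named for the array.

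The 2 groups were compared with lmFit and eBayes in limma (2-group means, 4 residual and 3.30 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 13064 probes and a threshold of adjusted p under 0.05. Adjusted p-values for genes come from this test unless the block or a list alone is named. Differences are log2 knockdown minus control. SE is the moderated standard error, and SD is over the 3 arrays of a group. A probe with no array of a group at detection p under 0.05 has only a bound there: the other group's mean was set against the mean of the lowest detected signal on each array, or the probe's own signal where higher, and is given as at least N-fold. Lists of genes, 27 in all, were tested with camera (preset inter-gene correlation 0.01), with camera and an estimated correlation, and with fry, which tests whether a list's genes move on balance in 1 direction. With an estimated correlation camera also tests on the few residual degrees of freedom of the fit. A call that it does not keep need not be lost to correlation. List p-values were adjusted over the 27 lists, and 1 list member had no match to a current symbol. The lists cover pluripotency (naive and core, formative and primed), ectoderm and neural, mesoderm, endoderm, trophectoderm, 2-cell stage and germ line genes, the nucleolar remodelling complex that Tip5 belongs to, RNA polymerase I and ribosome biogenesis, ribosomal proteins, Polycomb, DNA and H3K9 methylation, nucleosome remodellers, cell cycle, p53 targets, apoptosis, interferon response, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, stress response, fibroblast and feeder cells, epithelial state, imprinted genes, FGF-ERK targets, and Wnt, BMP, Nodal and LIF targets.

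The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Baz2a, the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose groups do not overlap, leaving out predicted and clone names, 7 pluripotency and partner genes whether or not they pass (Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42 and Smarca5, of which Smarca5 is not analysed here), and up to 4 called members of each list. Because 7 genes passed, the same rule was also applied to the fit with the replicate number as a block, an extension made after the data were seen.

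Replicate numbers come from the sample titles. Whether they pair the arrays was checked from the deviations of each array from its group mean across the 13064 probes. Control and knockdown arrays of the same number correlated at 0.44, 0.52 and 0.71 for replicates 1, 2 and 3, all over 0.1, so the numbers were taken to pair the arrays. Arrays of replicates 1 and 2 also correlated across numbers (0.37 and 0.46), and those of replicate 3 correlated with the others at between -0.62 and -0.52. The rule would therefore also pass with numbers 1 and 2 exchanged. It sets replicate 3 apart but cannot tell pair 1 from pair 2, whose pairing rests on the titles. Deviations cancel over the 3 arrays of a group. With replicate 3 apart in both groups, the signs of these correlations were therefore favoured beforehand. The fit with the replicate number as a block (2 residual and 3.90 prior degrees of freedom) was an alternative chosen beforehand, and its value is printed beside a result wherever it changes a call or moves a count by over 1.5 times.

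Mean probe signal was 544.0, 486.2 and 876.5 in control replicates 1, 2 and 3 and 529.4, 509.7 and 1092 in knockdown replicates 1, 2 and 3, and was 4.27 to 5.85 times the array's estimated background. Detected probes made up 48.5% to 52.3% of each array. The 2-group fit has no term for the brighter replicate 3 arrays, of which each group holds 1.

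The fits were tested on simulated data for this comparison, in 40 runs with 13064 probes, the real means and pair effects, and 200 probes changed by log2 0.5, 1 or 2. With variances drawn from the fitted prior, the 2-group fit recovered 0%, 0.112% and 56.6% of these and the blocked fit 0.112%, 25.9% and 94.3%, and 0.267% and 4.98% of their calls were false. With each probe's own moderated variance the shares recovered were 0%, 0.746% and 70.4% against 9.59%, 92.0% and 100%, and 0.0532% and 8.10% of calls were false. A list of 35 genes shifted by 0.5 was found by camera in 40 of the 40 runs. Noise was drawn independently for each probe. The runs therefore do not test camera on lists whose genes are correlated, as in the real data (estimated at up to 0.76). They also gave a probe the same noise variance on every array and the same change in every pair, which is the blocked fit's own model. In the real data the differences of pairs 1 and 2 correlated at 0.68, but those of pair 3 with them at 0.42 and 0.39. The shares recovered and false need not hold for these arrays.

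Alternatives were no background correction, median scaling, cyclic loess, an offset of 50, the authors' processed values, no filter, detection p under 0.01 on all 6 arrays, the replicate block, a variance trend with intensity, array weights, the mean of a gene's probes, a fold threshold of 1.5, other list tests, and leaving out each array. Added after seeing the data were a block for the replicate 3 arrays, replicates 1 and 2 only, quantile normalization after log2, and these settings combined with the replicate block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.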

Results

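The data are expression profiles of mouse E14 embryonic stem cells with Tip5 knocked down, set against cells given a control shRNA, with 3 arrays per group. Tip5, encoded by Baz2a, is the large subunit of a nucleolar chromatin remodelling complex. The comparison asks how expression differs when its level is lowered, and the series title names self-renewal and pluripotency as its subject. Values are normalized log2 levels, and a difference of 1 is a doubling.

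Baz2a, read by 1 probe, was 6.64 ± 0.78 (SD, n = 3) in controls and 5.02 ± 0.25 (SD, n = 3) in the knockdown, a log2 difference of -1.62 (SE 0.39), or 32.6% of the control level. The control arrays read 6.42, 7.51 and 5.99 in replicates 1, 2 and 3, and the knockdown arrays 5.21, 4.74 and 5.13, so the groups did not overlap. The probe was above background on 2 of the 3 knockdown arrays, near the floor of the measurement. The exact permutation test gave p = 0.1 (two-sided), the smallest p that 3 against 3 arrays allow. In limma the adjusted p was 0.203, and 0.0810 with the replicate block, so the difference did not pass the threshold in either fit. The size depends on the background correction: it was -0.53 with no background correction and -1.03 with an offset of 50.

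In the knockdown Fthl17f, Nlrp14, Plac8, Tuba3a, Dnajc5g, Xlr5a and Defb30 fell. With 2-group means, 9 probes in these 7 genes passed adjusted p under 0.05, all lower in the knockdown and all by at least 1.5-fold. Nlrp14, an oocyte and testis NLR family gene, fell by 3.26 (SE 0.32, adjusted p = 0.0280) from 10.01 ± 0.60 to 6.75 ± 0.23 (SD, n = 3, limma). Fthl17f, an X-linked ferritin-like gene, fell by 3.27 (SE 0.31, adjusted p = 0.0280), and Plac8 fell by 2.95 (SE 0.30, adjusted p = 0.0315). Tuba3a, a testis alpha-tubulin, fell by 2.79 (SE 0.24, adjusted p = 0.0236), and its 4 probes lay between -2.83 and -2.31.

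Dnajc5g, a testis member of the DNAJ family, was 7.42 ± 0.41 (SD, n = 3) in controls and above background on 0 of the 3 knockdown arrays, so it was at least 5.19-fold lower (limma adjusted p = 0.0236). Defb30, a beta-defensin, was likewise above background on 0 of the 3 knockdown arrays and at least 2.43-fold lower (adjusted p = 0.04996). Both bounds hold for the main processing only. Over the alternatives the log2 difference ranged from -2.97 to -0.98 for Dnajc5g and from -1.97 to -0.50 for Defb30. Xlr5a, of an X-linked lymphocyte-regulated family, fell by 2.24 (SE 0.25, adjusted p = 0.04996), and was above background on 2 of the 3 knockdown arrays. Tuba3a, Fthl17f, Xlr5a and Defb30 have close paralogs, so their probes can also read related transcripts. Each of these 7 genes was lower in the knockdown in all 3 replicate pairs. That follows from groups that did not overlap and is not separate support. No gene was called without control replicate 1, control replicate 2, knockdown replicate 1 or knockdown replicate 2 (595 to 780 genes at an unadjusted p under 0.05 in limma), 33 were called without control replicate 3 and 91 without knockdown replicate 3.

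With the replicate number as a block, 223 probes and 176 genes passed, 66 genes higher and 110 lower, and the 7 genes above were among them. All 176 moved the same way in the 3 pairs, which the blocked test favours, and in 158 the groups did not overlap. Over all 9015 genes tested, 17.0% had groups that did not overlap, where chance gives 10%. The blocked count was 16 without replicate 1, 0 without replicate 2 (1266 genes at an unadjusted p under 0.05 in limma) and 1143 without replicate 3.

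**Figure D1:**
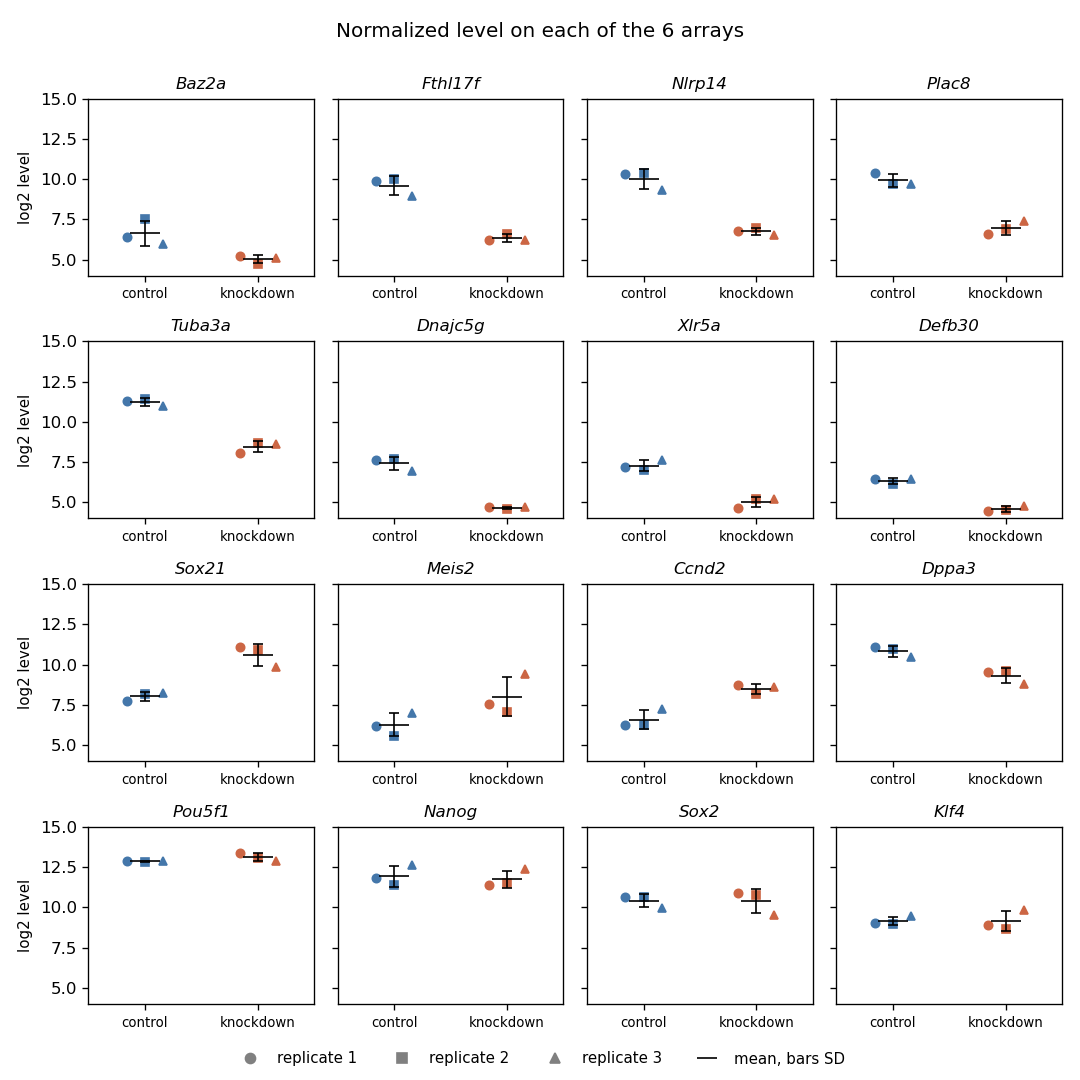
Normalized log2 level (vertical axis) of 16 genes on each array, by group, with a marker shape per replicate, the group mean as a line and the SD as bars (n = 3). Knockdown minus control is -3.26 for Nlrp14, -3.27 for Fthl17f and 2.56 for Sox21, and Pou5f1, Nanog, Sox2 and Klf4 differ by 0.25, -0.19, -0.03 and 0.01.

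Further genes that fell in the blocked fit included Pkd2l1 (-2.89), Efhc2 (-2.82), Crxos (-2.76), Defb42 (-2.76), Gpx2 (-2.74), Aire (-2.71) and Ldhc (-2.71), with blocked adjusted p from 0.0109 (Gpx2) to 0.0444 (Efhc2). Aire is the autoimmune regulator of the thymus, Ldhc the testis lactate dehydrogenase and Gpx2 a glutathione peroxidase. Efhc2 and Pkd2l1 were each above background on 2 of 3 knockdown arrays. The other probe of Aire gave -2.50, and the 3 probes of Ldhc lay between -2.71 and -2.02. These 7 genes had adjusted p from 0.0569 (Pkd2l1) to 0.172 (Defb42) with 2-group means, so that of these 2 fits only the block called them.

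The genes that rose furthest in the blocked fit were Sox21, Ccnd2, Tex13b, Meis2 and Meis1. Sox21, a neural SOX transcription factor, rose by 2.56 (SE 0.32, blocked adjusted p = 0.0335), with its other probe at 1.72. Meis2 and Meis1, homeobox partners of HOX proteins, rose by 1.75 (SE 0.23) and 1.71 (SE 0.19), with blocked adjusted p of 0.0342 and 0.0272. Ccnd2, cyclin D2, rose by 1.92 (SE 0.23, blocked adjusted p = 0.0299), and Lmo4 by 1.51, Irs2 by 1.40 and Car2 by 1.45. Tex13b (1.81), Svop (1.70), Irak3 (1.61), Zadh2 (1.60) and Defb25 (1.47) also rose. Tex13b was above background on 1 of 3 control arrays, and Svop and Defb25 on 2 of 3. With 2-group means the adjusted p of these 12 genes lay between 0.0569 (Lmo4 and Tex13b) and 0.376 (Meis2).

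The core pluripotency genes Pou5f1, Nanog, Sox2, Klf4, Esrrb and Zfp42 did not pass the test in either fit. Pou5f1 (Oct4) was 12.87 ± 0.03 in controls and 13.12 ± 0.24 in the knockdown (SD, n = 3), a difference of 0.25 (limma adjusted p = 0.764). Nanog differed by -0.19 (SE 0.39), Sox2 by -0.03 (SE 0.40), Klf4 by 0.01 (SE 0.33), Esrrb by 0.01 (SE 0.20) and Zfp42 by -0.05 (SE 0.30), with adjusted p between 0.943 and 0.996. The other probe of Sox2 gave 0.17, and the 3 probes of Klf4 lay between 0.01 and 0.20. The naive and core pluripotency list had a median difference of 0.02 over 31 genes, 18 positive and 13 negative (camera adjusted p = 0.986). No member passed with 2-group means, and adjusted over the list alone 1 fell. That gene, Dppa3 (Stella), a maternal factor and germ cell marker, differed by -1.51 (SE 0.29, adjusted p = 0.132) and passed with the block (adjusted p = 0.0202).

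Germ line genes were lower as a group in camera with its preset correlation, a call that an estimated correlation did not keep. Over 18 genes the median difference was -0.79 and 15 were negative (camera adjusted p = 2.84e-08, and 0.297 with an estimated correlation; 3.90e-06 and 0.579 with the block). It was -0.32 with no background correction and -0.31 with no filter, and fry gave an adjusted p of 0.0846. Tuba3a passed over all genes, with Tuba3b (-1.84) and Dppa3 in the block. Adjusted over the list alone, 8 fell with 2-group means and 11 with the block. Of these 8, named after their values were seen, Asz1 differed by -1.82, Rhox5 by -1.71, Zp3 by -0.97, and Sohlh2 by -0.80, while Prdm1, above background on 0 of 3 knockdown arrays, was at least 1.27-fold lower. Asz1 was above background on 1 of 3 knockdown arrays. The median was -1.06 in pair 1, -1.06 in pair 2 and -0.36 in pair 3.

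Cholesterol synthesis genes had a median difference of -0.54 over 19 genes, 17 of them negative (camera adjusted p = 7.41e-05, and 0.662 with an estimated correlation). No member passed over all genes with either fit. Adjusted over the list alone, 0 fell with 2-group means and 14 fell with the block, among them the sterol enzymes Lss (-0.61), Fdps (-0.65) and Sqle (-0.38, its other probe at -0.56), named after their values were seen. Hypoxia and glycolysis genes had a median of -0.34 over 25 genes, 23 negative (camera adjusted p = 1.15e-04, and 0.297 with an estimated correlation), and adjusted over the list alone 0 fell. With the block, 2 members fell over all genes, Pfkp, a phosphofructokinase (-1.52, its other probe at -1.30), and Egln3, a prolyl hydroxylase (-1.17), and 8 fell over the list alone. Without knockdown replicate 3 the cholesterol list had a median of -0.21 (camera adjusted p = 0.0535) and the hypoxia and glycolysis list -0.17, and without control replicate 3 the latter had -0.56.

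Interferon response genes had a median of -0.31 over 20 genes, 16 negative (camera adjusted p = 0.0159, and 0.494 with an estimated correlation), with no member called in either fit, and an adjusted p of 0.172 without knockdown replicate 3 and 0.0570 with array weights. The interferon median was -0.11 with no background correction (adjusted p = 0.0766), -0.093 with the strict filter (0.430) and -0.20 with replicates 1 and 2 only (0.126). Targets of p53 had a median of 0.22 over 26 genes, 21 positive (camera adjusted p = 0.0309, and 0.662 with an estimated correlation), with no member called over all genes in either fit. Over the list alone 0 passed with 2-group means, and with the block 3 rose and 1 fell. The p53 list's median was 0.08, 0.15 and 0.45 in pairs 1, 2 and 3, and its adjusted p was 0.358 without knockdown replicate 3 (median 0.12), 0.137 without control replicate 3, 0.0587 without control replicate 2, 0.300 with array weights (median 0.12), 0.0785 with the authors' values, 0.0575 with the mean of probes and 0.320 with replicates 1 and 2 only (median 0.11). Ectoderm and neural genes had a median of 0.42 over 11 genes, 9 positive (camera adjusted p = 0.0662, and 0.0391 with the block, where an estimated correlation gave an adjusted p of 0.579). Meis2 was the member called there, and 5 members rose over the list alone.

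**Figure D2:**
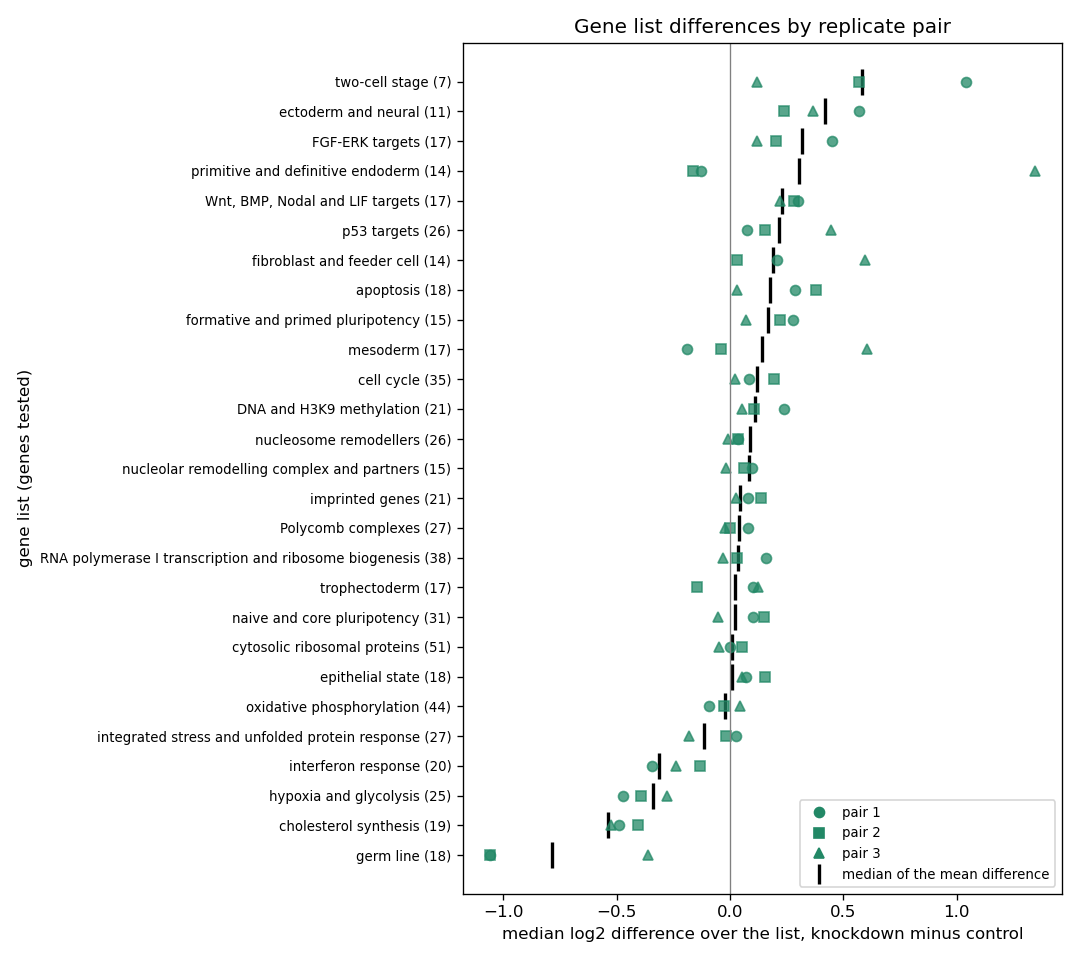
Median log2 difference, knockdown minus control (horizontal axis), of each of the 27 gene lists (vertical axis, with genes tested in brackets), for each replicate pair as a marker and for the mean over pairs as a bar. Germ line genes lie lowest, at -0.79, and the endoderm list lies at 1.34 in pair 3 against -0.13 and -0.17 in pairs 1 and 2.

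The other lists did not pass camera, a test of a shift in 1 direction, with either fit. Their medians and camera adjusted p were 0.58 and 0.775 for the 2-cell stage genes, 0.30 and 0.480 for endoderm, 0.14 and 0.485 for mesoderm, 0.02 and 0.813 for trophectoderm, 0.17 and 0.320 for formative and primed pluripotency, 0.32 and 0.320 for FGF-ERK targets and 0.23 and 0.193 for Wnt, BMP, Nodal and LIF targets. They were 0.08 and 0.813 for the Tip5 complex and partners, 0.03 and 0.320 for RNA polymerase I and ribosome biogenesis, 0.01 and 0.999 for ribosomal proteins, 0.04 and 0.813 for Polycomb, 0.11 and 0.247 for DNA and H3K9 methylation and 0.09 and 0.813 for nucleosome remodellers. For the remaining lists they were 0.12 and 0.262 (cell cycle), 0.18 and 0.162 (apoptosis), -0.02 and 0.480 (oxidative phosphorylation), -0.12 and 0.335 (stress response), 0.19 and 0.193 (fibroblast and feeder cells), 0.01 and 0.813 (epithelial state) and 0.04 and 0.883 (imprinted genes). Median, mean and test differed in sign for the Tip5 complex, ribosomal protein and imprinted lists. Fry also gives a test that counts moves in either direction. With 2-group means its adjusted p was 0.0063 for stress response and 0.0083 for fibroblast and feeder cells. With the block most lists passed it, such as nucleosome remodellers and naive and core pluripotency (fry adjusted p = 0.0124 each). Oxidative phosphorylation and imprinted genes also passed it there (fry adjusted p = 0.0437 and 0.0299). A pass with the block therefore hardly sets a list apart. Among members of the lists that did not pass, the block called Ccnd2 (1.92), Phlda1 (1.20), Ccn2 (1.19), Sp5 (1.07), Bmi1 (1.05), Pes1 (0.96) and Mbd1 (0.90, its other probe at 0.13) as higher. It called Nupr1 (-1.73) and Ier3 (-1.74) as lower, besides Dppa3 of the naive list.

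Replicate 3 stood apart in both groups. The first principal component held 52.8% of the variance and separated the replicate 3 arrays from the others, and the second held 28.4% and separated the groups. Across the 9015 genes the knockdown minus control differences of pairs 1 and 2 correlated at 0.68 (Pearson), those of pairs 1 and 3 at 0.42 and those of pairs 2 and 3 at 0.39, where genes are not independent replicates. Endoderm genes in knockdown replicate 3 reached 9.84 for Gata6, 11.86 for Col4a1 and 12.76 for Sparc. The highest of the other 5 arrays was control replicate 3, at 6.93, 9.38 and 11.71. These 3 genes were named after their values were seen. In 8 of the 14 endoderm members tested, both replicate 3 arrays lay above the other 4. With replicates 1 and 2 only, a choice made after seeing the data, 753 genes passed, and with the replicate 3 arrays as a batch block 398 passed.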

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

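The batch block, replicates 1 and 2 only, quantile normalization after log2 and all settings joined to the replicate block were chosen after seeing the data. Main counts were 9 probes and 7 genes, and 223 probes and 176 genes with the replicate block. Without the block, probe and gene counts were 4 and 2 (1 gene higher, 1 lower) with no background correction, 25 and 20 with cyclic loess, 28 and 23 (4 higher, 19 lower) with offset 50, 3 and 3 with the authors' processed values, 0 and 0 with no filter (1520 genes at an unadjusted p under 0.05 in limma), 29 and 24 with a variance trend and 1208 and 898 (397 higher, 501 lower) with array weights. The mean of probes gave 26 genes, the batch block 523 probes and 398 genes, and replicates 1 and 2 only 1010 probes and 753 genes. Leaving out 1 array gave 0 to 110 probes and 0 to 91 genes. The 7 genes kept their direction under each alternative that tested them, though they were chosen on these same arrays. With the replicate block the counts were 1048 and 801 with no background correction, 729 and 547 with median scaling, 479 and 367 with cyclic loess, 926 and 697 with offset 50, 97 and 76 with the authors' values, 55 and 46 with no filter, 556 and 422 (205 higher, 217 lower) with the strict filter, 1184 and 895 with a variance trend, 743 and 547 with array weights and 352 and 277 with quantile after log2. Leaving out replicate 1 gave 23 and 16, replicate 2 0 and 0, and replicate 3 1575 and 1143. The direction of all 176 genes was kept in each of these settings, of which the strict filter tested 113. These genes were called on the same arrays and moved 1 way in all 3 pairs. Leaving out a replicate could thus hardly turn them, and the kept direction is not separate support. Baz2a was lower under each of 19 alternatives (-1.88 to -0.53, adjusted p 0.0182 to 0.621), least with no background correction (-0.53) and at -1.03 with offset 50, and passed with array weights (-1.81, adjusted p = 0.0182) and replicates 1 and 2 only (-1.68, adjusted p = 0.0346); leaving out 1 array gave -1.88 to -1.22. The strict filter left Baz2a out.

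The 5 list calls kept their direction and lost significance with an estimated correlation and with fry: germ line -0.79 (adjusted p 0.297 and 0.0846), cholesterol synthesis -0.54 (0.662 and 0.306), hypoxia and glycolysis -0.34 (0.297 and 0.133), interferon -0.31 (0.494 and 0.190) and p53 targets 0.22 (0.662 and 0.306). For hypoxia and glycolysis the estimate was 0.02, near the preset 0.01, yet the unadjusted camera p went from 1.27e-05 to 0.0164. More than the correlation thus differs between these camera tests. The interferon call was also lost with no background correction (-0.11), the strict filter (-0.093) and replicates 1 and 2 only (-0.20), and the p53 call with the authors' values (0.24), the mean of probes (0.19) and replicates 1 and 2 only (0.11). The germ line median was -0.32 with no background correction and -0.31 with no filter, and interferon had -0.11 with no filter and -0.18 with offset 50, all with the call kept. With array weights the interferon (-0.32, adjusted p = 0.0570) and p53 calls (0.12, adjusted p = 0.300) were lost. The ectoderm list passed with median scaling (0.35) and the replicate block (0.42), and the endoderm list with no filter (0.30). Leaving out 1 array changed calls for cholesterol synthesis (-0.65 to -0.21), ectoderm (0.21 to 0.66), fibroblast genes (0.0082 to 0.34), interferon (-0.37 to -0.31), p53 targets (0.12 to 0.27) and Wnt, BMP, Nodal and LIF targets (0.15 to 0.32), and moved hypoxia and glycolysis (-0.56 to -0.17) with the call kept. For the lists with no call in these settings it gave 0.075 to 0.33 for formative and primed pluripotency, 0.080 to 0.34 for FGF-ERK targets, 0.092 to 0.19 for mesoderm, -0.027 to 0.14 for the Tip5 complex, 0.0060 to 0.16 for RNA polymerase I, 0.066 to 0.14 for DNA and H3K9 methylation, 0.022 to 0.11 for nucleosome remodellers, 0.052 to 0.20 for cell cycle, 0.16 to 0.27 for apoptosis, -0.087 to -0.0038 for oxidative phosphorylation and -0.12 to -0.025 for stress response. The block changed no other list call. The cause of these changes was not tested, except that fewer arrays or probes follow from the settings that drop them. The median over all genes moved by under 0.1 in each setting. A slide block was not run, since no slide was given in the sources used here. Signals 4.27 to 5.85 times background limit dim genes such as Baz2a.

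The endoderm list, past the threshold with no filter (0.30), had the other direction with array weights (-0.12), with replicates 1 and 2 only and without knockdown replicate 3. Lists and genes that missed the threshold both as reported and under the alternative turned direction in 36 values of lists and 21 of genes, the cause of which was not tested. Direction is that of the test, which for a list can differ from the sign of its median. The naive list gave -0.013 with median scaling, 0.048 with the authors' values, 0.011 with no filter and 0.016 with the strict filter. With the strict filter mesoderm gave -0.062, trophectoderm 0.022, Polycomb 0.031 and imprinted genes 0.12, and imprinted genes gave 0.043 with the block. Ribosomal proteins gave 0.0091 with fry, no filter, a variance trend, the replicate block and the batch block, 0.020 with array weights, 0.0090 with offset 50, 0.0092 with quantile after log2 and 0.030 with replicates 1 and 2 only, where endoderm gave -0.15. Esrrb gave -0.066 with median scaling and -0.0073 with the authors' values, Klf4 -0.0048 with cyclic loess and -0.16 with array weights, and Sox2 0.048 with the authors' values, 0.15 with array weights, 0.071 with the mean of probes and 0.20 with replicates 1 and 2 only. Leaving out 1 array gave the ranges -0.052 to 0.16 for the naive list, -0.34 to 0.67 for endoderm, -0.019 to 0.11 for trophectoderm, -0.067 to 1.34 for the 2-cell stage, -0.042 to 0.044 for ribosomal proteins, -0.044 to 0.13 for Polycomb, -0.13 to 0.17 for epithelial genes and -0.22 to 0.10 for imprinted genes, and -0.52 to 0.16 for Nanog, -0.28 to 0.42 for Sox2, -0.34 to 0.25 for Klf4, -0.10 to 0.17 for Esrrb and -0.28 to 0.17 for Zfp42.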

Other observations

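The tests of replicate pairs and the neighbour test without shared family names were chosen after the results were seen. Genes of the 2-cell stage, the cleavage-stage programme that a small share of embryonic stem cells enters, marked replicate 3 in both groups: 6 of 7 members tested were higher on both of its arrays than on the other 4. Zscan4c read 12.58 in control replicate 3 against 9.69 and 9.99 in controls 1 and 2, and 13.21 in knockdown replicate 3 against 11.29 and 11.09. Tcstv1 read 11.23 against 6.55 and 6.42 in controls. Of the 7 members, 6, 5 and 5 were higher in the knockdown in pairs 1, 2 and 3. Zscan4c was 1.60, 1.10 and 0.63 higher and Tmem92 1.24, 1.31 and 0.65 higher, while Tcstv3 differed by 0.96, 0.05 and -0.18. No member passed over all genes with either fit. Adjusted over the list alone, 0 members rose with 2-group means and 3 with the block (Tcstv1, Tmem92 and Zscan4c). Tdpoz1, above background on 0 of 3 knockdown arrays, fell over the list alone in both fits.

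The first pattern is the lower germ line list. Replicate 3 as its source would leave pairs 1 and 2 near 0, and the higher of their 2 medians was -1.06. A bias of dim probes would move other genes of the same level. The list's median lay at percentile 0 of 10000 random lists matched on mean level, whose central 95% spanned -0.16 to 0.20. Random lists lack the correlation among a list's own genes, estimated at 0.14 for germ line, so the percentile does not bear on chance. Lists that camera did not call also lay far out, such as the 2-cell stage at percentile 100 and FGF-ERK targets at 99.9. A shift of the culture out of the naive state is not decided by the naive list, of which 18 genes were positive and 13 negative, while Dppa3 differed by -1.51 and the formative and primed list by 0.17. An effect of the knockdown on these genes may therefore stand as a hypothesis, and such a shift, cross-reading among paralogs, off-target effects of the shRNAs and chance stay open.

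The second pattern is the separation of replicate 3. The endoderm list's median was 1.34 in pair 3, with 12 of 14 members higher, against -0.13 and -0.17 in pairs 1 and 2. In 8 of the 14 both replicate 3 arrays lay above the other 4, so part of the rise was shared with control replicate 3. The list was singled out because of its pair 3 median, so no test here decides whether endoderm-like cells grew in the culture of knockdown replicate 3. The abundant members Sparc, Lama1 and Col4a1 rose there by 1.05, 1.63 and 2.48, while Apoe differed by -0.15 and Apoa1, above background on 3 of the 6 arrays, by -0.59. For the rest of the replicate 3 difference, array brightness, labelling and culture day are confounded and stay open.

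The third pattern is the lower cholesterol synthesis and glycolysis lists. A single pair as the source would leave another near 0, and the highest pair medians were -0.40 for cholesterol synthesis and -0.28 for hypoxia and glycolysis. Cholesterol synthesis was also lower in replicate 3 of both groups. Its mean level was 9.82, 9.78 and 9.27 in control replicates 1, 2 and 3. In knockdown replicates 1, 2 and 3 it was 9.31, 9.44 and 8.67. Its groups thus overlapped, though it fell within each pair. For hypoxia and glycolysis the groups did not overlap in mean level. A bias tied to signal level would move matched lists too, and both lists lay at percentile 0 of 10000. As for germ line, the percentile does not bear on chance. The estimated correlation was 0.43 for cholesterol synthesis and 0.02 for hypoxia and glycolysis. Cell density and medium at harvest, which may move both lists, were not tested.

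Genes called as lower lay near each other more often than random draws, and those called as higher did not pass this test. Of the 110 genes lower in the blocked fit, 23 had another among the 2 nearest tested genes on either side in gene order of GRCm38.p6, against a mean of 5.24 in 10000 random draws (permutation p = 1e-04, one-sided, the smallest they can give). With neighbours of a shared family name left out the number was 18 (permutation p = 5e-04), with pairs such as Mapt and Myl4, Hormad2 and Osm, and Cpn1 and Pkd2l1, where the other probes of Mapt and Osm gave -0.37 and -0.32. A family was read from the letters before the first digit, so a paralog under a predicted name counts as another family. The predicted genes Gm5134 and Gm14685 were among the 18, so family clusters may remain. For the 66 higher genes it was 4 against a mean of 1.91 (permutation p = 0.243). The draws were not matched on expression level or variability, so they show clustering beyond unmatched genes and not its source. Regional effects on the genes that fell may be worth a test in other data.

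The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 9 probes and 7 genes, 1 split each, and the highest of the others 0 and 0. For lists past camera's threshold the real split gave 5, 3 splits gave as many, and the highest other was 8, in the split that set control 1, control 2 and knockdown 2 against the rest and so kept both replicate 3 arrays together; with the block 6 lists passed. The smallest camera p of the other splits was 1.33e-08 for germ line (1.05e-09 in the real split), 5.73e-06 for cholesterol synthesis (5.49e-06) and 5.17e-04 for hypoxia and glycolysis (1.27e-05), where the germ line split differs from the real one in pair 3 only. Among the 4 splits that part all 3 pairs, the real one gave 223 probes and 176 genes and the highest other 0 and 0, again too few splits for a share under 0.05; the others swap control and knockdown in 1 or 2 pairs.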
